A study of Drosophila melanogaster with 3 samples.

How the data were processed

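RNA from ovaries of Drosophila melanogaster was measured on 3 Agilent arrays with 2 colours. Per the labels, channel 1 (Cy3) held RNA of ovaries whose germ line came from sva53 mutant pole cells, and channel 2 (Cy5) held RNA of ovaries whose germ line came from sva53/+ pole cells. The mutant pole cells came from embryos of germline clones homozygous for the allele, and both kinds were moved into host embryos laid by osk mutant females. Each mutant sample pooled 2 pairs of ovaries from an independent experiment, so n = 3. The control was a single RNA from 3 pairs of ovaries, hybridised to all 3 arrays as a common reference. Per the labels, flies were about 7 days old, RNA was purified on silica columns, and 100 ng of total RNA was amplified linearly before labelling.

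The deposited values were log10 ratios of the 2 channels, 1 per feature and array, for 22575 features. Agilent Feature Extraction 7.1 made them, per the submitters' processing notes. Background correction, dye normalisation and filters are not given in the sources used here. The scale was read from the values: both signs, a lowest value of exactly -2 and exact zeros, as this software writes them. Outside the edge of the grid the median log10 ratio was 0 on each array, so no centring was added. An exact 0 stood at 344, 216 and 99 features of arrays 1, 2 and 3, and such a value may stand for a ratio that was not measured. The labels name the dyes but not the numerator. This software writes red (Cy5) over green (Cy3), so the deposited ratio was read as control over mutant, and its sign was turned to give log2 of mutant over control. That direction is likely, not stated. If the numerator was Cy3, every sign in the text turns and each count of higher features becomes the count of lower ones.

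All 3 arrays carried the mutant in the same dye, so a dye bias of a feature does not cancel. The reference is 1 control sample, so the test of the ratio against 0 leaves out the control's own spread. The number of arrays limits the precision.

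Features were named through the platform annotation paired with the value table: 17329 features had 1 gene, 326 had several genes or no symbol, and 4284 outside the grid edge were not listed and are unnamed here. Of 10805 genes, 10801 matched the RefSeq gene table of assembly GCF_000001215.4 (Release 6 plus ISO1 MT) by gene identifier, and 0 symbols changed. The 636 features at the outer edge of the grid, none of them annotated, were left out. Features of 1 gene were averaged on the log2 scale (5531 genes had 2 or more), and others stayed as they were, which gave 15415 features.

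Each feature was tested with limma 3.58.1 in R 4.3.3 (lmFit with an intercept and eBayes, 2-sided) with a Benjamini-Hochberg adjusted p under 0.05. Calls are of this test, SDs are over the 3 arrays, and values are log2 ratios of mutant over control. Gene lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 22 lists. The lists covered germ plasm, the piRNA pathway, meiosis, germline stem cells, maternal axis patterning, eggshell, yolk, follicle cells, ecdysone, DNA replication and cell cycle, ribosomal proteins, the mitochondrial respiratory chain, the proteasome, antimicrobial response, heat shock, cell death and DNA damage, testis, muscle, fat body, midgut, hemocytes with basement membrane, and the reproductive tract. Counts of members are also given adjusted over the list alone. Near-identical copies, such as the Hsp70 genes, cannot be separated with certainty by a hybridisation.

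Genes were named by a rule set before the data were examined, as were the tests, the lists and most alternatives. It took the 12 highest and the 12 lowest called genes by mean log2 ratio, with the same sign on all arrays. It also took up to 2 highest and 2 lowest called members of each list, or, where none was called, the 2 members with the smallest unadjusted p. A fixed set was always looked at: mamo, vas, nos, osk, bam, Yp1, Yp2, Yp3, Sxl, otu, bru1, piwi, aub and c(3)G. Of these, vas, nos, Sxl and bru1 had no feature of their own under these names and were not analysed here. Other genes named in the text were chosen after their values were seen.

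The alternatives were centring or scaling each array, a robust prior, array weights, single features or the feature with the smallest SD for each gene, removal of exact zeros, an adjusted p under 0.01, a test against a fold of 1.5, and leaving out each array. Lists were also tested with an estimated correlation, with fry, and without members shared between lists. A removal of trends over grid rows and columns, and lists without named paralogs, were added after seeing the data.

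The procedure was tested on simulated data for the comparison of sva53 with sva53/+ over 15415 features, 200 of them changed. It recovered 34.3% of the changes of 1.5-fold, 68.7% of those of 2-fold and 95.5% of those of 4-fold, with 3 false calls. These rates do not cover a deviation of the single control RNA or a dye bias. Either would repeat on all 3 arrays and could be called as a change. A simulated list shifted by 0.4 on the log2 scale was called, and 0 of 20 unshifted lists were. Tables and figures used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.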

Results

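Gene expression was compared between ovaries carrying a germ line homozygous for sva53 and ovaries carrying an sva53/+ germ line. The design asks which transcripts differ when the germ line lacks the normal allele. The mutant pole cells came from embryos of homozygous germline clones, so they also lacked the normal maternal product. Whether the sva53/+ pole cells came from such mothers is not given here. A maternal effect therefore cannot be told apart from the genotype of the germ line itself. Only the germ line came from the moved pole cells, so follicle cells and other somatic cells were host cells in both channels. A ratio of a gene made in somatic cells is therefore not a change within mutant cells. The mutant was sampled in 3 independent pools, each set against the same control RNA. Pearson correlations of the log ratios across features were 0.635 for arrays 1 and 2, 0.566 for arrays 1 and 3, and 0.644 for arrays 2 and 3, where features are not independent replicates. The shared control alone gives a positive value: simulated pools with no change, the same spread as the control and no array noise had a mean r of 0.50. Independent noise of the arrays would lower that value, while a wider deviation of the control RNA or a shared dye bias would raise it. The correlations therefore cannot show a change in the mutant. The SD of the log2 ratios was 0.49 on array 1, 0.35 on array 2 and 0.34 on array 3. Directions are likely and rest on the deposited ratio being red over green; with the other numerator all of them turn.

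Bulli had the highest mean, at 2.56 ± 0.23 log2 (SD, n = 3; 5.91-fold). The heat shock chaperone genes Hsp70Bc (2.33 ± 0.90) and Hsp70Ab (2.29 ± 0.90) rose, as near-identical copies whose signals are uncertain to separate, and Hsp70Ab (1.53) was not called when its feature of smallest SD was used. RpS19b, a paralog of a ribosomal protein gene, had the lowest mean, at -2.65 ± 0.88 (6.27-fold). Ranks depended on the arrays: without array 2 Hsp70Bc read 2.80 and Bulli 2.57. With array weights Hsp70Bc read 1.71, Hsp70Ab 1.65, RpS19b -2.003 and CG17376 -2.15. Hira, which encodes a histone chaperone, fell by 2.18 on the log2 scale (SD 0.11, n = 3), and ATPsynepsilonL, a paralog of an ATP synthase subunit gene, by 2.13 (SD 0.05).

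The other genes with large increases were CG10208 (2.38), flip (2.22, features at 2.65 and 1.80), the glutathione transferase genes GstD3 (1.96) and GstD8 (1.28), CG5080 (1.95, features at 1.479 and 2.414), CG13101 (1.34), the adenylyl cyclase gene rut (1.34), the cytochrome P450 gene Cyp4e2 (1.29) and CG32243 (1.27). The other large decreases were in CG10654 (-2.41, or -1.71 with array weights), the cap-binding factor gene eIF4E3 (-2.24, features at -2.54 and -1.94), CG17376 (-2.23), HP6 (-1.99), CG32572 (-1.98), the intraflagellar transport gene Oseg5 (-1.96), blanks (-1.96), CG15599 (-1.87) and the ribosomal protein paralog RpL22-like (-1.87). Hira has 2 features, which gave -1.22 and -3.15, and RpL22-like has 2, which gave -3.28 and -0.45, so the size of both changes is uncertain.

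**Figure D1:**
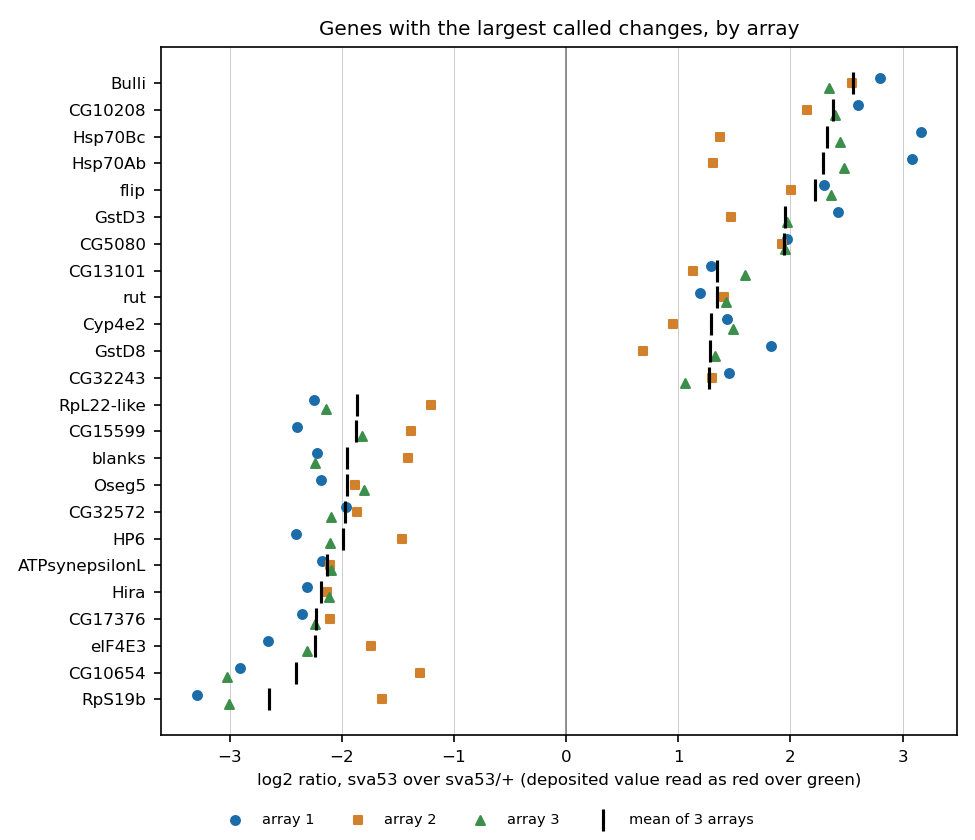
Log2 ratios of sva53 over sva53/+ (x axis, deposited value read as red over green) of the 12 called genes with the highest and the 12 with the lowest mean, 1 marker per array and a bar at the mean of 3 arrays. Means run from 2.56 for Bulli to -2.65 for RpS19b, and each gene has the same sign on all 3 arrays.

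In total 2135 of 15415 features passed an adjusted p under 0.05 with limma, 1021 higher and 1114 lower in the mutant (1114 higher and 1021 lower with the sign turned). Of 10805 genes, 687 rose and 761 fell (761 and 687 with the sign turned). All 1448 had the same sign on 3 arrays, which follows from the threshold, since mixed signs leave too wide a spread to pass. The median size of the called changes was 0.445 log2. Changes of at least 2-fold were called in 180 features, 56 higher and 124 lower (124 and 56 with the sign turned), and of at least 4-fold in 20, 10 on each side. The lowest adjusted p with limma was 0.0123. With any 1 array left out, limma called 0 features, while 4710, 3277 and 4304 had an unadjusted p under 0.05 without arrays 1, 2 and 3. Among genes named by the fixed rule, GstD8, gnu, brat, dib, LysX, Irbp and LanA were not called with a robust prior, gnu not with centred arrays, and brat and Hr39 not with scaled arrays.

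The sva53 allele is recalled as belonging to mamo, a gene for a BTB zinc-finger protein, which the labels do not state. The single feature of mamo gave -0.30, -0.49 and 0.50 on arrays 1, 2 and 3, and the mean of -0.10 ± 0.53 (SD, n = 3) did not pass (adjusted p 0.78 with limma). Its mean was 0.01 without array 1, 0.10 without array 2 and -0.396 without array 3. Whether the lesion changes the level of that transcript is not known here, so the feature does not check the labels.

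Of 45 measured genes of DNA replication and the cell cycle 17 rose, 0 fell and 28 did not pass; adjusted over the list alone, 25 rose and 0 fell. RnrL, the large subunit of ribonucleotide reductase, rose by 0.88, the mitotic kinase gene aurB by 0.78 and the replicative helicase gene dpa by 0.72. The list mean was 0.30 and camera in limma gave an adjusted p of 2.66e-08 at the preset correlation of 0.01. The correlation estimated between members was 0.314, and camera with that estimate gave an adjusted p of 0.752.

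Meiosis and recombination genes had 11 of 40 members higher and 2 lower, with 27 not passing; adjusted over the list alone, 17 were higher and 3 lower. The kinesin-like gene nod (0.65) and trem (0.61), needed for meiotic double-strand breaks, rose. The genes that fell were cona (-1.08) and c(3)G (-0.37 ± 0.09), both encoding parts of the synaptonemal complex, against the direction of the list. With its feature of smallest SD c(3)G read -0.21 and was not called. The adjusted p was 0.00165 with camera in limma, and 0.752 with an estimated correlation of 0.065.

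Of 93 genes listed by name as cytosolic ribosomal proteins, 36 were measured. Among these 13 fell, 0 rose and 23 did not pass, and adjusted over the list alone 18 fell and 0 rose. The match by name also took in genes such as RpLP0-like (-0.73) and RpL7-like (-0.51), both among those that fell. The largest decreases were in the paralogs RpS19b (-2.65), RpL22-like (-1.87, features at -3.28 and -0.45) and RpL37-2 (-1.22), while RpL32 fell by 0.44. The list mean was -0.40 (adjusted p 2.04e-07 with camera in limma, and 0.752 with an estimated correlation of 0.355). Without named paralogs, left out after seeing the values, 6 of 24 members fell and the mean was -0.19 (adjusted p 0.000286).

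Genes of the mitochondrial respiratory chain fell in 19 of 72 members, rose in 1 and did not pass in 52; adjusted over the list alone, 34 fell and 2 rose. ATPsynepsilonL (-2.13) and ATPsynbetaL (-0.64), paralogs of ATP synthase genes, had the largest decreases, and COX6AL (0.39) was the member that rose. The 2 features of COX6AL read 0.73 and 0.05, and it was not called with the latter, which had the smallest SD. ND-B17.2, for a subunit of complex I, fell by 0.49. The list mean was -0.22 (adjusted p 2.09e-09 with camera in limma, and 0.748 with an estimated correlation of 0.063). Without named paralogs 15 of 54 members fell and the mean was -0.20 (adjusted p 2.1e-08).

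Testis and male germline genes fell in 8 of 36 members and rose in 0, with 28 not passing; adjusted over the list alone, 13 fell and 0 rose. The sperm-leucylaminopeptidase genes S-Lap2 (-1.47) and S-Lap7 (-1.05, features at -0.67 and -1.43) had the largest decreases, and topi, a regulator of male meiosis genes, fell by 0.63. The list mean was -0.26 and was below 0 on each array (-0.21, -0.28 and -0.28). The adjusted p was 0.000363 with camera in limma, and 0.748 with an estimated correlation of -0.004.

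Proteasome genes rose in 4 of 38 members and fell in 1, with 33 not passing; adjusted over the list alone, 3 rose and 1 fell. Rpn2 (0.55) and Prosalpha2 (0.51) rose, and Rpt4R, a paralog of an ATPase subunit gene, fell by 1.44. The list mean was 0.12, and 0.23, 0.14 and -0.01 on arrays 1, 2 and 3. The adjusted p was 0.0028 with camera in limma, and 0.802 with an estimated correlation of 0.532. Without array 1 the mean was 0.06 and without array 3 it was 0.18. The adjusted p was 0.0505 without array 1, the highest of 10 alternatives with the preset correlation, which went down to 1.38e-05. Without named paralogs 4 of 25 members rose, 0 fell, and the mean was 0.25 (adjusted p 1.38e-05).

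Eggshell genes, made by follicle cells around late egg chambers, differed between the arrays. Each array held 1 mutant pool, so a difference of the pool cannot be told apart from one of the array or its labelling. The mean of the 24 vitelline membrane and chorion genes was -2.13 on array 1, -0.32 on array 2 and 0.07 on array 3. Fcp3C read -4.73, 0.50 and -1.33, and the chorion gene Cp38 read -2.87, -0.47 and 0.81. Only the peroxidase gene Pxt passed (0.59), 0 members fell, 23 did not pass, and adjusted over the list alone 0 rose and 0 fell. The list was called lower (mean -0.79, adjusted p 0.0285 with camera in limma at the preset correlation of 0.01). With the estimated correlation, 0.764, the adjusted p from camera was 0.802. Without array 1 its mean was -0.12 and its adjusted p 0.517, in a range from 0.000577 to 0.517 over 10 alternatives of which 7 passed. It also missed the threshold without members shared between lists (0.057) and with the feature of smallest SD per gene (0.0583).

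**Figure D2:**
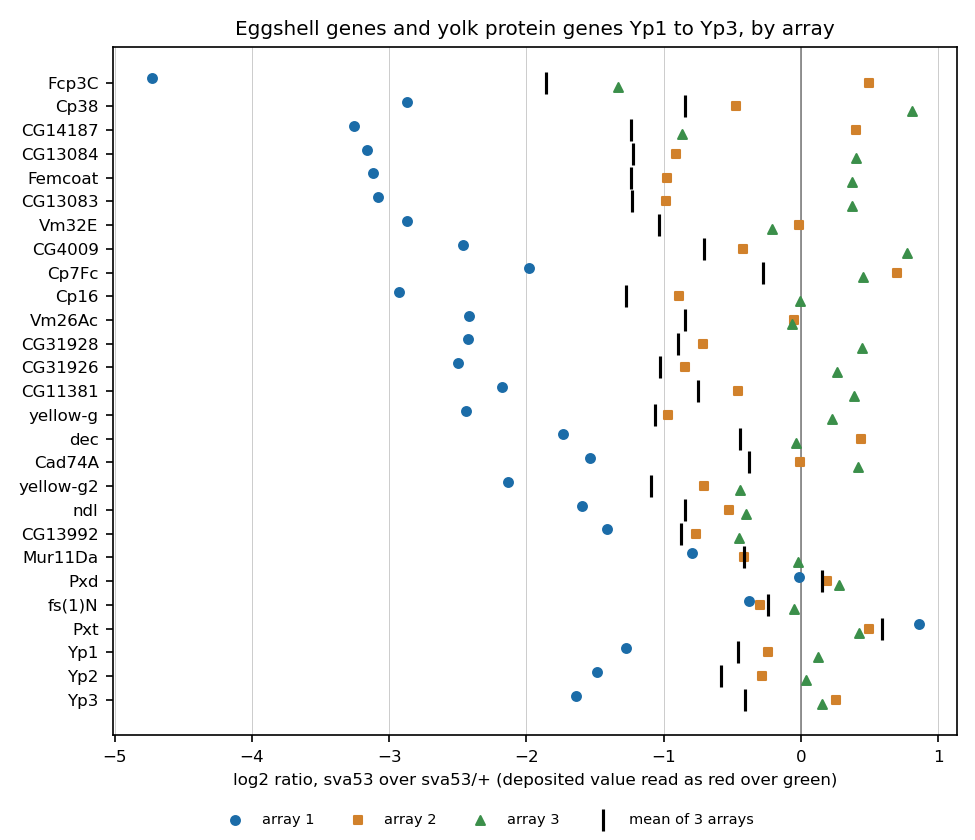
Log2 ratios of sva53 over sva53/+ (x axis, deposited value read as red over green) of 24 eggshell genes and the yolk protein genes Yp1, Yp2 and Yp3, 1 marker per array and a bar at the mean. On array 1, 23 of the 24 eggshell genes lie lower than on both other arrays.

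Yp1 read -1.27, -0.24 and 0.13 on arrays 1, 2 and 3, Yp2 read -1.49, -0.29 and 0.04, and Yp3 read -1.64, 0.26 and 0.16, and these did not pass. Of the 4 features of Yp1, 1 read 0.20 on array 1 and the others lay between -1.81 and -1.74. In the list of 7 yolk genes dsx rose (0.37), boca fell (-0.28) and 5 did not pass, with the same counts adjusted over the list alone. The dsx value rested on 1 feature at 1.21, with the others between 0.00 and 0.15, and dsx was not called with its feature of smallest SD (0.10). The list mean (-0.14) and median (-0.28) lay below 0 while camera in limma placed it above (adjusted p 0.825). Without array 1 the mean was 0.09.

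Among 35 germ plasm and germline RNA regulators, 7 rose, 2 fell and 26 did not pass; adjusted over the list alone, 8 rose and 3 fell. Rbp9 (0.72), needed for germline cyst differentiation, and the translational repressor gene cup (0.46) rose, while bgcn, a partner of bam in stem cell daughters, fell by 1.44 and gnu by 0.29. The 2 features of Rbp9 read 0.20 and 1.24, and it was not called with the former, which had the smallest SD. The list did not pass (adjusted p 0.387 with camera in limma). Values that did not pass were -0.12 for osk, 0.11 for bam, 0.05 for otu, 0.02 for piwi and -0.17 for aub. The germline stem cell list had 3 of 32 members higher, among them brat (0.43), and 2 lower, bgcn and the BMP ligand gene gbb (-0.45), with the same counts adjusted over the list alone. Its mean was -0.02 (0.003 without array 1), its median 0.03 and camera's direction upward (adjusted p 0.637). In the piRNA pathway, Hen1 (0.41) rose, papi (-0.39) fell and 25 of 27 did not pass (adjusted p 0.256), and adjusted over the list alone 0 rose and 1 fell. Maternal axis genes had 3 of 28 members higher and 0 lower, with the same counts adjusted over the list alone, among them hb (0.50, features at 0.72 and 0.27) and tub (0.49), and the list did not pass (adjusted p 0.479).

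In follicle cell genes, the actin-bundling gene sn (0.57) and neur (0.45, features at 0.64 and 0.25) rose, and peb (-0.81), cas (-0.59) and ct (-0.38), for transcription factors, fell, with 16 of 21 not passing. The 2 features of cas read -0.96 and -0.23, and it was not called with the latter, which had the smallest SD. Adjusted over the list alone 3 rose and 5 fell (adjusted p 0.565 with camera in limma for the list). Of 19 ecdysone genes, the receptor gene EcR (0.38) and Hr39 (0.38) rose, and GstE14 (-0.97) and dib (-0.35), both needed for ecdysone synthesis, fell. The 4 features of EcR lay between 0.15 and 0.79, and 1 of the 4 of Hr39 had the opposite sign (-0.41). Adjusted over the list alone, 3 rose and 2 fell, and the list did not pass (adjusted p 0.637).

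Heat shock and protein folding genes rose in 5 of 16 members. Besides the Hsp70 copies these were Hsp27 (1.24), Hsp26 (0.81) and Droj2 (0.33). DnaJ-1 was called lower (-1.17), but its 2 features disagreed, at 0.28 and -2.62. Adjusted over the list alone 6 rose and 1 fell, and the list did not pass (mean 0.38, adjusted p 0.0746 with camera in limma). It passed with the feature of smallest SD per gene (0.00903), 1 of 10 alternatives, which reached 0.118. Of 26 genes of cell death and DNA damage, 4 rose and 0 fell, with the same counts adjusted over the list alone, led by the end-joining genes Irbp (0.59) and Ku80 (0.50). The 2 features of Ku80 read 0.87 and 0.13, and it was not called with the latter, which had the smallest SD. The list mean was 0.03 (0.008 without array 3) and its median -0.004, camera pointed upward, and the adjusted p was 0.637 with limma. Antimicrobial genes had 0 of 22 higher and 2 lower, DptB (-0.45) and LysX (-0.32), with 0 higher and 1 lower adjusted over the list alone. Their mean was 0.06 (0.11 without array 1 and 0.007 without array 2), camera pointed upward and fry downward (adjusted p 0.798 with camera in limma).

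Lists of other tissues were measured for cells that ovary dissections could hold. Basement membrane genes LanA (-1.17), Col4a1 (-1.09), vkg (-1.04), SPARC (-0.93) and LanB2 (-0.71) fell. They were the 5 called of 19 in the hemocyte and basement membrane list, with 0 higher and the same counts adjusted over the list alone. All called members were thus basement membrane genes, so they do not by themselves show a difference in carried-over hemocytes. With its feature of smallest SD Col4a1 read -0.78 and was not called. Fat body genes Pepck1 (-1.80), Lsd-1 (-1.71) and Obp99b (-1.52) fell, 3 of 15, with 1 higher and 3 lower adjusted over the list alone. Neither list passed (adjusted p 0.243 and 0.241 with camera in limma), while both did without array 2 (0.0214 and 0.0169), 1 of 10 alternatives each, which reached 0.517 and 0.555 without array 1. Both means were lowest on array 1, at -0.53 and -0.68. Over the 3 arrays the list means were -0.27 and -0.35, while the medians over members were -0.07 and -0.10. Muscle genes had 0 of 21 called, with limma and adjusted over the list alone, the smallest p being those of Argk1 (0.36) and Act79B (-0.22), both called with their features of smallest SD (0.32 and -0.35) and with array weights, and Argk1 also with scaled arrays, and the list did not pass (adjusted p 0.116 with camera in limma). Without array 1 it passed (0.00794), 1 of 10 alternatives, which reached 0.386. Of 36 midgut genes, etaTry (0.42) rose and Jon65Aiv (-1.27) and Jon44E (-0.35) fell (adjusted p 0.365). Of 15 reproductive tract genes, Hr39 rose and Send1 fell by 0.37 (adjusted p 0.565). For these lists the counts were the same adjusted over the list alone.

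**Figure D3:**
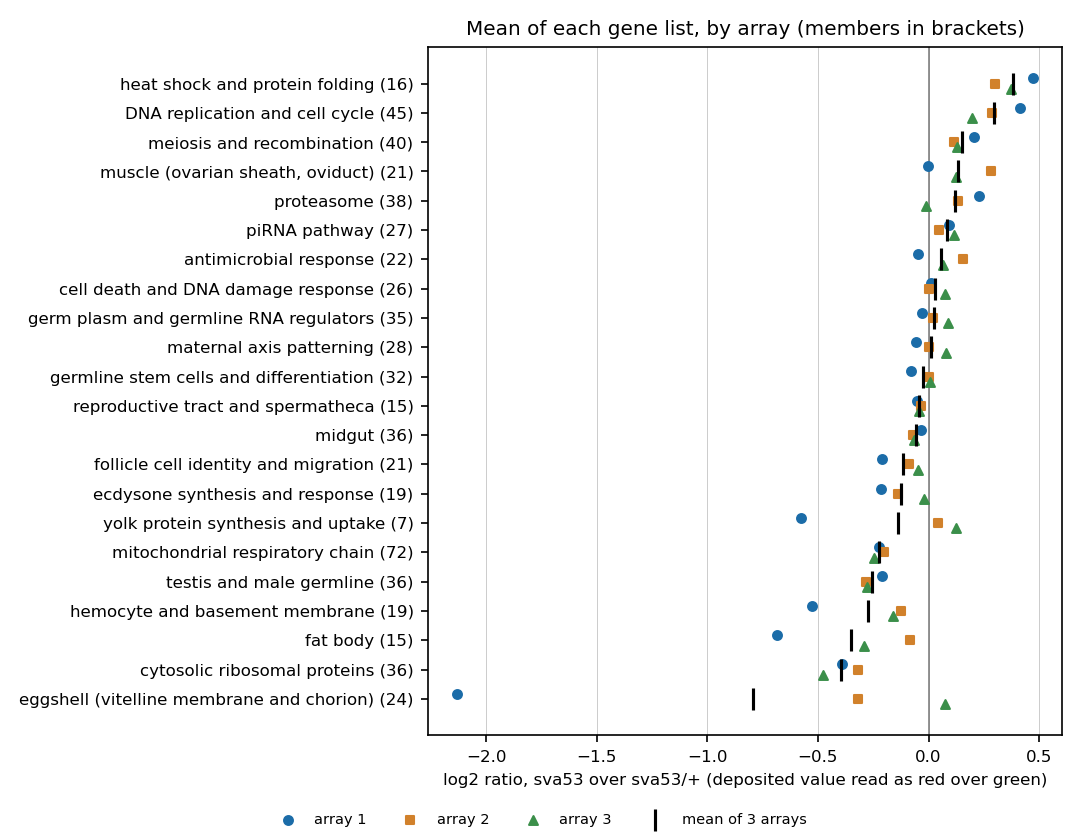
Mean log2 ratio of sva53 over sva53/+ (x axis, deposited value read as red over green) of each of 22 gene lists, with the number of measured members in brackets, 1 marker per array and a bar at the mean. The eggshell list spans -2.13 to 0.07 over arrays, while the DNA replication list stays above 0 and the ribosomal list below 0 on all 3.

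Of the 22 lists 7 passed with camera in limma, 0 with an estimated correlation and 2 with fry, which tests whether a list moves on balance one way: the mitochondrial respiratory chain and the testis list (adjusted p 0.0398 for both). With an estimated correlation camera takes its degrees of freedom from the 3 arrays, so few lists could pass. The testis list went from 0.000363 to 0.748 in camera although its estimate, -0.004, lay below the preset 0.01. So the 0 does not show that correlation between genes made the calls. The estimates for DNA replication, ribosomal, proteasome and eggshell genes (0.314, 0.355, 0.532 and 0.764) lay far above the preset, so their preset p may be too small.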

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

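The tests of array 1 and of the X chromosome, and those of sign turns and dye bias, were chosen after the results they bear on were seen; the test of neighbouring genes was set before its count was known.

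Among the 636 features at the outer edge of the grid, which were left out and carry no gene name, 322 had strong ratios on the arrays, with a median log10 ratio of -1.437 as deposited. The remaining 314 had a median of -0.148.

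Eggshell genes stood apart on array 1, where 23 of 24 were lower than on both other arrays, against 34.6% of all genes. Of 43 genes at least 4-fold lower on array 1 than the mean of the others, 15 were eggshell genes. After removal of trends over the grid the eggshell mean of array 1 remained below that of array 2 (difference -1.82 log2), and after scaling all arrays to one spread the difference was -1.46 (-1.459), which argues against position and spread as the whole cause. Another share of late egg chambers in mutant pool 1 may be behind it, since Yp1, Yp2 and Yp3 shifted the same way by a mean of -1.475 log2, although 1 of the 4 Yp1 features did not (0.20 on array 1). Fat body, which also makes yolk proteins, stays open as another source of the yolk protein shift. The fat body list (-0.68, -0.08 and -0.29 on arrays 1, 2 and 3) and the hemocyte list (-0.53, -0.13 and -0.16) were lowest on array 1 too. Their medians over members were -0.10 and -0.07, against means of -0.35 and -0.27, so a few members carry much of both means. The 5 called members of the hemocyte list were basement membrane genes. Whether a differing share of egg chambers or fat body reflects the genotype, the age of single flies or the dissection was not tested.

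Features past the threshold numbered 2135, and turning the sign of 1 array in turn gave at most 0 calls with limma. The real signs gave the highest count, 1 of 4 patterns, and 4 patterns are too few for a share under 0.05. Any oddity of the single control RNA, or a dye bias of single features, could also give a ratio that repeats on 3 arrays, and turning signs does not address either. Of 759 called genes with several features, 95.7% had all features on one side. Features of a gene were averaged before the test, so genes whose features disagreed tended to drop out of the calls. The selection itself thus raises this share. The sequences of those features are not known here, so a bias shared by overlapping features cannot be told apart from a change in the ovary, and the control's own spread stays open by design.

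Called genes of at least 2-fold numbered 123, 32 higher and 91 lower. They formed 5 neighbouring pairs in the gene order of assembly GCF_000001215.4, against a mean of 1.33 in 10000 shuffles (one-sided permutation p 0.0101). Pairs of adjacent genes with one name stem were left out. A linked difference in genetic background of the pole cells could give such an excess among genes expressed in the germ line. Somatic cells were host cells in both channels, so it could not act directly on neighbours expressed there. Where the genes of each pair are expressed was not tested. Related neighbours that the name rule missed could also give an excess. The pairs were vkg with Col4a1, Prx6c with CG11825, CG11825 with Prx6b, CG32706 with CG6999, and CG15599 with CG8128. Prx6c and Prx6b share a name stem and lie on either side of CG11825, and vkg and Col4a1 are both basement membrane genes. The excess therefore depends on how families are counted, and shared regulation or common descent of neighbours stays open. The pairs were first sought for changes of nearly equal size on all arrays, but held 1 of the 24 genes with an SD under 0.15, of which 6 lay on the X against a mean of 3.6 in shuffles (one-sided permutation p 0.132). On the X, which carries mamo, lay 18 of the 123, against a mean of 18.3 in shuffles (one-sided permutation p 0.57). This count argues against background differences of the X that act on genes of the X itself as the source of most of them. Differences on the X that act on genes of other chromosomes would not raise the count, so they stay open. Smaller changes stay open too, since 249 of all 1448 called genes lay on the X against a mean of 214.4 (one-sided permutation p 0.0044).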

How the results depend on the processing

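Feature counts were recomputed under each alternative run, named genes under all but the test of single features, and lists under centring, scaling, member, feature, zero and array settings and the other set tests. The removal of grid trends and the lists without paralogs were chosen after seeing the data. Counts stayed within 1.5 times the 2135 calls when arrays were centred (2214) or scaled (2853), with a robust prior (1919), without exact zeros (2447) and without grid trends (2337). Array weights gave 5804 calls (2869 higher, 2935 lower), with weights of 0.438, 3.42 and 0.666 for arrays 1, 2 and 3. Single features gave 3338 (1730 higher), and the feature with the smallest SD per gene 3418 (1660 higher, 1758 lower). With limma an adjusted p under 0.01 left 0 calls, 0 higher and 0 lower (5588 at an unadjusted p under 0.05), and a test against a fold of 1.5 left 15 (5 higher, 10 lower). Leaving out any array gave 0 calls in either direction, where fewer arrays leave less to estimate the spread. The values of mamo ran from -0.396 to 0.098 when an array was left out (0.006 without array 1). Of the 7 list calls, 0 held with an estimated correlation, where the 3 arrays leave camera too few degrees of freedom for most lists to pass. With fry 2 held. The counts without arrays 1, 2 and 3 were 5, 7 and 7, where 6, 9 and 7 of all lists passed. With the feature of smallest SD, 9 named genes lost their call (DnaJ-1, Hsp70Ab, Rbp9, c(3)G, dsx, cas, COX6AL, Ku80 and Col4a1), with adjusted p from 0.0523 to 0.356 with limma, and 2 gained one (Argk1 and Act79B), as they did with array weights, and Argk1 with scaling. With a robust prior 7 lost their call, with centring 1 and with scaling 2. Signs turned with the feature of smallest SD for DnaJ-1 (0.284), osk (0.025), Yp1 (0.114), otu (-0.032) and piwi (-0.054). Yp3 turned with array weights (0.061) and without array 1 (0.208, range from -0.74), and otu (-0.065, range to 0.153) and piwi (-0.046, range to 0.104) turned without array 3. Of these only DnaJ-1 was called, its smallest-SD feature did not pass, and apart from the number of arrays the cause was not tested. A filter on 2 arrays and a run without centring were not run, since no value was missing and no centring was used. Signal over background was not analysed here.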

Other observations

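The groups counted here were chosen after their values were seen and were not tested for enrichment. Of 28 glutathione transferase genes 5 rose and 2 fell: GstD3 (1.96), GstD8 (1.28), GstD10 (1.21), GstE11 (0.78) and GstD2 (0.57) rose, and GstE14 (-0.97) and GstE13 (-0.60) fell. GstD genes are close relatives, so signals of single members are uncertain. Of 78 cytochrome P450 genes 10 rose and 2 fell, a called share of 15.4% against 13.4% of all genes. Cyp4e2 (1.29), Cyp6a20 (1.12) and Cyp6a21 (1.05) had the largest increases, and Cyp4p2 fell by 1.56 on the log2 scale (SD 0.12, n = 3).

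In 7 measured genes of the synaptonemal complex and the chromosome axis, SMC1 rose (0.33) while cona and c(3)G fell, the latter not called with its feature of smallest SD. In 7 basement membrane genes 5 fell and 0 rose, with a median of -0.93, and LanA (-1.76), Col4a1 (-1.53) and vkg (-1.52) had their lowest values on array 1.

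Of the 123 called genes of at least 2-fold, 24 had an SD under 0.15 over the arrays and 34 had one of at least 0.4. The smallest change was on array 2 in 64 of them (52.0%). Among the 5 measured genes on either side of mamo in the gene order, CG12479 (-0.32) and betaNACtes1 (-0.63) were called. Around Hira, ct (-0.38) and CG12155 (0.37) were called.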
